A study of Bos taurus with 31 samples.

How the data were processed

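RNA sequencing was performed on mammary epithelial organoids, the clusters of epithelial cells left after enzymatic digestion of gland tissue, prepared from biopsies of dairy cows. Per the labels, 15 libraries came from virgin animals at 14 months of age and 16 from lactating animals at 40 to 60 days in lactation. The 31 libraries came from 16 cows, of which 15 gave a library at both stages and 1 (animal 495) only a lactating one. Per the labels' protocols, poly-A RNA was made into strand-specific libraries and synthetic spike-in RNA was added.

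The values used were read counts per gene, deposited by the authors as whole numbers with no normalization. A second deposited table held RPKM values, which the authors had scaled by an effective library size, with their log2 fold changes and adjusted p-values. The deposited log2 fold changes were coded virgin minus lactating, as judged from the RPKM values of the same table. Per the submitters' processing notes, HISAT2 2.0, SAMtools, StringTie 1.3.2, featureCounts 1.5.2, edgeR and genome build UMD3.1 were used. Their roles and settings, and the adjustment behind the p-values, are not given in the sources used here. Of the 14084 deposited p-values, 10132 were exactly 1.

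The count table held 14084 rows. Rows with identical counts in every library were taken as 1 counted locus listed under several names, which left 13407 distinct loci, 592 of them listed more than once. One mitochondrial locus was listed in 7 rows. A locus length was recovered for each row from the ratio of count to RPKM, and was whole to within 1.63e-09. Among 11861 tested rows whose symbol has a length in the RefSeq table, 1023 (8.62%) had a locus over 2 times that length, so counts of neighbouring or overlapping genes may be joined there. Of the rows, 1086 had only an Ensembl identifier as name, and 0 of these could be named from the RefSeq table. No coordinates are printed, because the reference table was of another build. Total counts per library over all rows ranged from about 20128400 to 60114500 in virgin and from about 26827000 to 72138400 in lactating samples. With each locus counted once, the ranges were 12477600 to 38794100 and 17637500 to 45478600. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom was 35.0 for virgin and 45.5 for lactating pairs.

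Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Rows were filtered by filterByExpr (minimum count 10, minimum total 15), which kept 13180 rows (12504 distinct loci) and left out 904. TMM factors, estimateDisp, glmQLFit with robust estimation and glmQLFTest were used with group as the only term, and Benjamini-Hochberg adjusted p-values under 0.05 were called. A change over 2-fold was tested with glmTreat against a log2 fold change of 1. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. Positive log2 fold changes are higher in lactation. CPM values were computed over the TMM-scaled library and are given with their SD over the libraries of a group.

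The 27 gene lists were fixed before the data were examined, as were the tests and the rule for named genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes were the 12 largest rises and 12 largest falls among called genes with a symbol, an average log2 CPM of at least 2 and the same direction in all 15 animals. To these were added the 4 members of each list with the smallest p, the called member against each list's main direction, and a fixed set of caseins, receptors and transcription factors. The share of counts in milk protein genes was compared by a two-sided permutation test with 100000 resamples. The wording fixed for that share was the percent of all counts in genes. It was read with each locus counted once, and the value over every row is given beside it.

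The replicate number in the labels is the animal, so it pairs the samples, per the series design. After removal of group means, the 15 lactating libraries correlated with the virgin library of their own animal at 0.0702 to 0.392 (mean 0.221), against a mean of -0.016 with those of other animals. The correlation was over 0.1 for 12 of 15 pairs, and 9 of 15 lactating libraries correlated best with their own animal. The fit with the animal as a block was made as an alternative on 30 samples.

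The edgeR steps were tested on simulated data for the lactating against virgin comparison, with 200 of 13143 rows changed. Counts were drawn from each row's mean over all libraries and the real library sizes and dispersions. Of 50 rows changed 1.5-fold, 19 were recovered, and of 50 changed 2-fold, 43 were recovered. Of 50 changed 4-fold 49 were recovered, and of 50 changed 8-fold 50 were. Among the 168 calls, 7 were unchanged rows (4.17%). All other rows had equal means in both groups, and the simulated libraries were not paired. These rates thus hold for a comparison with few changes and no shift in composition, which the real one is not. Alternatives covered the scaling, the filter on low counts, the block on the animal, the animals whose virgin library has a letter after its number, DESeq2 1.42.0 and limma-voom. Alternatives chosen after seeing the data counted repeated loci once or left out libraries L478 and L538, V479 and V490, V502, V509, or each library in turn (named by stage letter and animal number). Scaling by spike-in RNA was not run, because no spike-in rows were analysed here. MKI67, PGR and the 12 genes of the red blood cell list were not analysed here.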

Results

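Gene expression was measured by RNA sequencing in mammary epithelial organoids from 16 dairy cows, in 15 libraries taken when the animals were virgin heifers and 16 taken in lactation. The organoids are clusters of mammary epithelium freed from biopsy tissue by enzymatic digestion, and 15 animals gave both stages. With each locus counted once, total counts ranged from about 12477600 to 38794100 per virgin library and from about 17637500 to 45478600 per lactating library. Single libraries are named by the letter of their stage and the number of their animal, so that V502 and L502 are the virgin and lactating libraries of 1 cow. The comparison addressed how gene expression in the mammary epithelium of the same cows differs between the virgin and the lactating stage. Every lactating library was taken later in the animal's life, after calving. Stage therefore cannot be told apart from age, parity or time of sampling here, also within animals.

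Genes for milk proteins were among those with the largest rises. CSN2 (ENSBTAG00000002632), which encodes beta-casein, stood at 93079 ± 84155 CPM (SD, n = 16) in lactating and 119.5 ± 313 CPM (SD, n = 15) in virgin libraries, a log2 fold change of 9.60 ± 1.49 (SE; edgeR adjusted p = 2.71e-06). CSN1S1 (alpha-S1-casein) rose by 9.96 ± 1.48 on the log2 scale (edgeR adjusted p = 1.34e-06), and LALBA (ENSBTAG00000005859), the regulatory subunit of lactose synthase, by 10.71 ± 1.42 (edgeR adjusted p = 2.13e-07). GLYCAM1, a mucin-like milk glycoprotein, rose by 11.29 ± 1.41 and PAEP (beta-lactoglobulin) by 8.36 ± 1.49. Each of these 5 genes was higher in 15 of 15 animals. CSN3 (kappa-casein), at 347 ± 189 CPM already in virgin libraries, rose by 6.19 ± 0.52, and CSN1S2 (alpha-S2-casein) by 10.87 ± 1.69. Of the 14 tested members of the milk protein list, 13 rose, 0 fell and 1 was not called, with 13 risen when adjusted over the list alone (camera adjusted p = 1.93e-11; adjusted p = 0.192 with an estimated correlation). The fitted rises of several of these genes depended on single virgin libraries. Without V509 the log2 fold change of CSN2 was 11.12, of PAEP 11.14, of CSN1S1 10.91, of BTN1A1 8.78 and of MUC15 8.90. Without V479 that of CSN1S2 was 11.93, and that of GLYCAM1 was 11.93 or more when V479 or V490 was left out in turn. LALBA was counted over a locus 43.7 times its RefSeq length.

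The share of all counts that fell on milk protein genes was 25.2% ± 18.3 (SD, n = 16) in lactating and 0.436% ± 0.196 (SD, n = 15) in virgin libraries. The difference of 24.7 percentage points had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. With every row in the total, repeated loci included, the difference was 17.4 points. Lactating libraries ranged from 1.08% to 52.1%, with L478 (1.43%) and L538 (1.08%) lowest. L490, L504, L531, L581 and L615 lay at 5.40% to 11.8%, and all remaining lactating libraries at 26.5% or more. The lactating mean and SD thus join separate ranges. Without L478 and L538 the difference was 28.2 points.

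**Figure D1:**
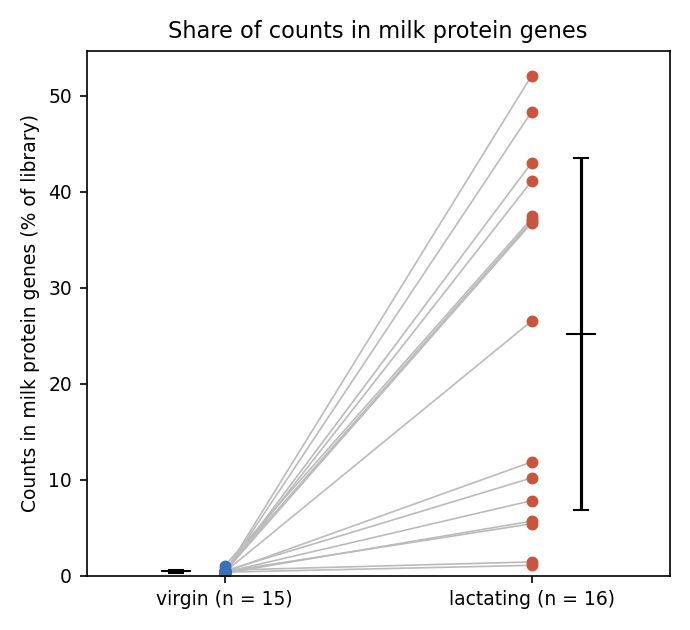
Percent of each library's counts that fell on the milk protein list (y axis, %), with each locus counted once, in virgin and lactating libraries (x axis). Points are libraries, grey lines join both stages of an animal and black bars are mean ± SD. Virgin libraries lie between 0.261% and 1.03%, and lactating libraries between 1.08% and 52.1%.

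Across the table, 3189 of 13180 rows were higher and 4069 lower in lactation (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 710 were higher and 369 lower by more than 2-fold. Counts of called members in a gene list are to be read against the 3189 and 4069 of 13180 rows called here, since a list can reach such shares without differing from other genes. Of called genes with a symbol and an average log2 CPM of at least 2, 677 rose and 492 fell in every one of the 15 animals. The excess of lower rows was absent with the animal as a block (3666 higher and 3656 lower) and with limma-voom (3691 and 3598). Without TMM factors the median log2 fold change of all rows moved by -0.48, and the counts became 1389 higher and 7751 lower, a split of 15.2% higher against 43.9% with them. All changes given here are with TMM factors, and so relative to that shift. For changes over 2-fold the corresponding shares were 24.9% and 65.8%. In the authors' deposited table, 1520 rows were higher and 1457 lower in lactation at an adjusted p under 0.05. Of the 2785 calls in the authors' deposited table that were tested here, 2785 were called in the same direction. Both rest on the same counts, so this was likely beforehand. The adjustment behind the deposited p-values is not given, so the numbers of calls are not like for like.

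Among other genes with an average log2 CPM of at least 2 that rose in all 15 animals, FABP3, a fatty acid binding protein, rose by 8.08 ± 0.75 (SE; edgeR adjusted p = 3.43e-10) on the log2 scale. BTN1A1, butyrophilin of the milk fat globule membrane, rose by 6.79 ± 1.05, MUC15 by 7.77 ± 0.84 and MUC1, a membrane mucin, by 6.73 ± 0.57. HSTN, which lies among the casein genes, rose by 10.83 ± 1.02 (11.56 without V490) and CRISP3, a secreted cysteine-rich protein, by 7.94 ± 0.72. Of the casein cluster neighbours, 4 of 6 rose and 2 were not called, with 4 risen when adjusted over the list alone, and 4 rose and 2 fell without TMM factors (camera adjusted p = 0.00589; adjusted p = 0.192 with an estimated correlation). The 4 include JCHAIN, the immunoglobulin joining chain made by plasma cells (2.87 ± 0.53, higher in 14 of 15 animals, and 3.90 without V581). FABP3 was counted over a locus 8.17 times its RefSeq length.

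Of genes of milk fat synthesis and secretion, 21 of 30 tested members rose, 3 fell and 6 were not called, with 21 risen and 3 fallen when adjusted over the list alone. Without TMM factors 14 rose and 3 fell. CD36, a fatty acid translocase, rose by 3.37 ± 0.32, ACSL1, which activates long-chain fatty acids, by 2.03 ± 0.17, and PLIN2, a lipid droplet coat protein, by 1.78 ± 0.18. ACLY, which makes cytosolic acetyl-CoA from citrate, fell by 1.07 ± 0.11 and was lower in 15 of 15 animals (edgeR adjusted p = 1.94e-09). The list's camera adjusted p was 4.85e-05 (adjusted p = 0.192 with an estimated correlation). Of the calcium, phosphate and zinc genes, 10 of 16 rose and 2 fell (10 and 3 when adjusted over the list alone, 8 and 5 without TMM factors). They included ATP2C2, a secretory pathway calcium pump (4.28 ± 0.42), the zinc transporter SLC30A4 (1.64 ± 0.13) and the phosphate transporter SLC20A1 (1.33 ± 0.14). STC2, a stanniocalcin, fell by 3.80 ± 0.51. The camera adjusted p of that list was 0.00546 (adjusted p = 0.192 with an estimated correlation).

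Other metabolic lists were divided. Of 23 cholesterol synthesis genes, 10 rose and 1 fell (8 and 1 when adjusted over the list alone, 2 and 9 without TMM factors), and INSIG1, a regulator of sterol synthesis, rose by 2.57 ± 0.44 over a locus 2.19 times its RefSeq length. Their median was 0.29, and -0.24 without TMM factors (camera adjusted p = 0.0971, and 0.0356 without L478 and L538). Of 15 genes of lactose synthesis and glucose uptake, 5 rose and 1 fell (5 and 1 when adjusted over the list alone, 4 and 6 without TMM factors). Without V479 and V490 8 rose and 1 fell (camera adjusted p = 0.0277). B4GALT1, the catalytic subunit of lactose synthase, rose by 0.91 ± 0.15 and SLC2A1, a glucose transporter, by 1.01 ± 0.26. The median of that list was 0.22, and -0.26 without TMM factors. Its camera adjusted p was 0.0620, and 0.0465 with the animal as a block, a fit of 30 libraries without L495 (without L495 and no block 0.0539; adjusted p = 0.323 with the block and an estimated correlation). Of 15 amino acid transporters, 4 rose and 2 fell, with the same counts when adjusted over the list alone, and 7 rose and 2 fell with the animal as a block, against 3 and 5 without TMM factors. Their median was 0.27, and -0.30 without TMM factors. Camera, which compares a list with the other genes, gave the direction as up in both (adjusted p = 0.0924, and 0.0344 without TMM factors). SLC7A4, of the cationic amino acid transporter family, rose by 4.25 ± 0.48 over a locus 2.09 times its RefSeq length, and SLC38A3, a glutamine transporter, by 3.78 ± 0.39, while SLC38A1, also a glutamine transporter, fell by 1.51 ± 0.20.

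Most genes of oestrogen and progesterone sensing fell. ESR1 (ENSBTAG00000007159), oestrogen receptor alpha, went from 66.3 ± 60.8 CPM in virgin to 10.9 ± 6.97 CPM in lactating libraries (log2 fold change -2.59 ± 0.38, edgeR adjusted p = 9.82e-07, lower in 14 of 15 animals). GREB1, an oestrogen-induced gene, had a log2 fold change of -5.23 ± 0.42 and MYB, a transcription factor, of -2.09 ± 0.22. TFF3, a secreted trefoil peptide, went the other way (3.73 ± 0.52, over a locus 3.18 times its RefSeq length). Of the 16 tested members, 11 fell, 2 rose and 3 were not called, with 11 fallen when adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.192 with an estimated correlation). Outside that list, among called genes with a symbol and an average log2 CPM of at least 2 that fell in all 15 animals, the furthest falls were those of SORCS1, a sorting receptor (-5.40 ± 0.40, edgeR adjusted p = 5.48e-12), SLC44A4, a choline transporter-like protein (-4.87 ± 0.49), and SV2B, a synaptic vesicle protein (-4.82 ± 0.30). The membrane progestin receptor PAQR7 (-4.23 ± 0.55), the adhesion molecule NRCAM (-4.09 ± 0.36) and the lysyl oxidase LOXL4 (-3.96 ± 0.30) followed under the same limits.

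Of 19 genes of prolactin and growth hormone signalling, 9 rose and 3 fell, with the same counts when adjusted over the list alone and 3 and 7 without TMM factors (camera adjusted p = 0.0891). Their median was 0.24, and -0.23 without TMM factors. IRS1, an insulin receptor substrate, rose by 1.84 ± 0.18 and SOCS3, an inhibitor of cytokine signalling, by 1.27 ± 0.20, while GHR, the growth hormone receptor, fell by 1.21 ± 0.14. ELF5, a transcription factor of alveolar cells, rose by 1.03 ± 0.33 (edgeR adjusted p = 0.00996) and was higher in 10 of 15 animals, over a locus 3.57 times its RefSeq length. That call was lost without TMM factors (0.43, adjusted p = 0.165) and without the animals whose virgin library has a lettered title (0.97, adjusted p = 0.0604). PRLR, the prolactin receptor, had a log2 fold change of -0.59 ± 0.24 (edgeR adjusted p = 0.0391), and the call was lost when any 1 of 10 lactating or 6 virgin libraries was left out. Without L495 its adjusted p was 0.0606, and 0.0700 with the block, which also lacks L495. STAT5A (0.24 ± 0.17, edgeR adjusted p = 0.243) and STAT5B (0.13 ± 0.11, adjusted p = 0.325), which carry the prolactin signal to the nucleus, were not called. Without TMM factors they stood at -0.25 (adjusted p = 0.113) and -0.36 (adjusted p = 0.00500). Neither was called without L478 and L538.

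Cell cycle genes fell in 19 of 29 cases, rose in 2 and were not called in 8, with 21 fallen when adjusted over the list alone, and 27 fallen and 0 risen without TMM factors (camera adjusted p = 0.00164; adjusted p = 0.427 with an estimated correlation). The mean log2 CPM of the list was highest in V509 (3.03) and V502 (2.90), and the list's median of -0.87 became -0.64 without V509 and -0.69 without V502, with 16 and 18 fallen, and -0.66 with the animal as a block, with 17 fallen. With a stricter filter of 1 CPM in 15 libraries, 11 of 21 tested members fell, with a median of -0.50. The replication licensing genes MCM2 (-1.16 ± 0.20) and MCM3 (-1.05 ± 0.17) were lower in 15 of 15 animals each, and PCNA, the sliding clamp of DNA polymerase, rose by 0.72 ± 0.12, a call lost without TMM factors (0.25, adjusted p = 0.198). Of 24 genes of protein folding in the endoplasmic reticulum, 13 fell and 4 rose, with the same counts when adjusted over the list alone, and 17 fell and 1 rose without TMM factors (camera adjusted p = 0.199). HYOU1, a chaperone, fell by 1.48 ± 0.17 and CREB3L1, a transcription factor of the endoplasmic reticulum, rose by 1.44 ± 0.22. Of 35 ribosomal protein genes, 11 fell, 1 when adjusted over the list alone and 4 with the animal as a block, while 35 fell without TMM factors (median -0.71, against -0.29 with them). RPSA fell by 0.59 ± 0.16 and the list's camera adjusted p was 0.0680, 0.0475 without the animals whose virgin library has a lettered title and 4.43e-04 without TMM factors. Reads of these genes can be shared with processed pseudogenes. Of 29 chromatin regulators, 11 fell and 4 rose, with the same counts when adjusted over the list alone, and 22 fell and 2 rose without TMM factors (camera adjusted p = 0.156). SUV39H1, a histone methyltransferase, fell by 1.26 ± 0.14 and EZH2, another, rose by 1.25 ± 0.21.

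Endothelial markers rose in 15 of 16 cases, also when adjusted over the list alone, with a median log2 fold change of 2.17 (camera adjusted p = 3.51e-07; adjusted p = 0.308 with an estimated correlation). KDR (ENSBTAG00000000782), a vascular growth factor receptor, rose by 2.31 ± 0.30 and CDH5, the cadherin of endothelial junctions, by 2.45 ± 0.40, each in 15 of 15 animals. Lymphocyte markers rose in 13 of 14 cases (14 when adjusted over the list alone), among them CD8A of cytotoxic T cells (2.61 ± 0.23) and CD4 of helper T cells (2.15 ± 0.30), at 1.53 ± 0.601 and 1.04 ± 0.510 CPM in lactation (camera adjusted p = 1.01e-07; adjusted p = 0.192 with an estimated correlation). Macrophage and monocyte markers rose in 13 of 16 cases, also when adjusted over the list alone (12 rose and 1 fell without TMM factors), with CSF1R, the receptor of macrophage colony stimulating factor, at 2.11 ± 0.27 and MRC1, a mannose receptor, at 2.19 ± 0.31 (camera adjusted p = 1.18e-06; adjusted p = 0.192 with an estimated correlation). Of the 14 adipocyte markers listed, 8 were tested. Of these 5 rose and 1 fell, the same when adjusted over the list alone, against 2 and 2 without TMM factors. The list's camera adjusted p was 0.106, and 0.0198 without TMM factors. FABP4, a fatty acid binding protein, rose by 4.38 ± 0.65, or by 5.17 without V502. The member that fell was PLIN1, a lipid droplet coat protein (-1.18 ± 0.20, lower in 14 of 15 animals). Of 7 plasma cell markers 5 rose and 2 fell (camera adjusted p = 0.0971, and 0.0204 without TMM factors), and of 9 neutrophil markers 5 rose and 1 fell (camera adjusted p = 0.0889, 0.0105 without TMM factors and 0.0350 with the stricter filter of 1 CPM in 15 libraries), with the same counts in both when adjusted over the list alone.

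**Figure D2:**
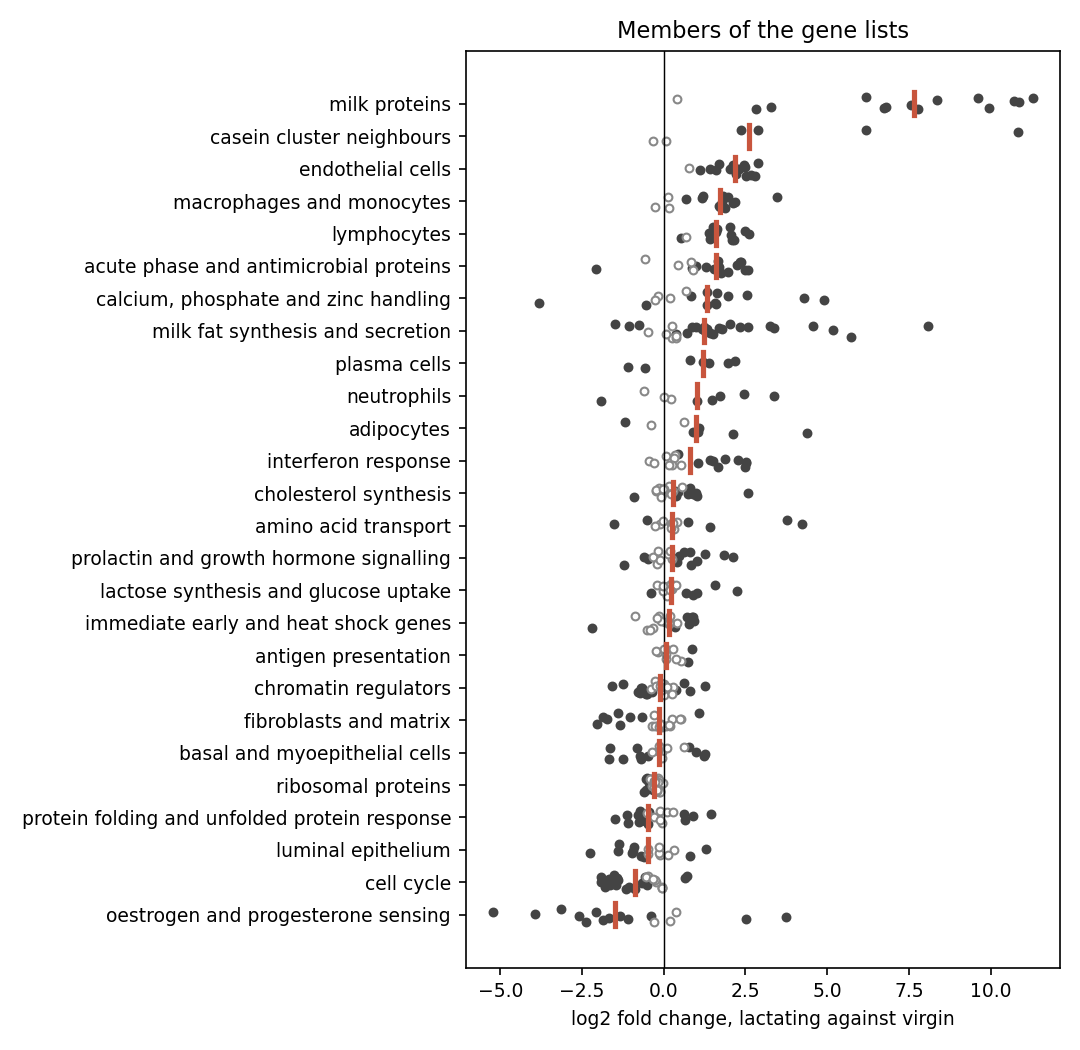
Log2 fold change in lactating against virgin libraries (x axis) of each tested member of the gene lists (y axis). Filled points passed the edgeR test, open points did not, and red bars are list medians, which run from 7.67 for milk proteins to -1.50 for oestrogen and progesterone sensing.

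Luminal epithelial markers fell in 8 of 17 cases and rose in 2, with the same counts when adjusted over the list alone, and 12 fell and 1 rose without TMM factors (camera adjusted p = 0.199). The keratins KRT18 (-2.24 ± 0.37) and KRT7 (-1.40 ± 0.24) were lower in 13 and 14 of 15 animals, while KIT, a receptor of luminal progenitors, rose by 0.79 ± 0.13, a call lost without TMM factors (0.32, adjusted p = 0.104). Of 18 basal and myoepithelial markers 7 fell and 4 rose, also when adjusted over the list alone, and 11 fell and 2 rose without TMM factors (camera adjusted p = 0.717, direction down, and 0.989, direction up, without TMM factors), with P-cadherin CDH3 at -1.63 ± 0.17 and the transcription factor SNAI2 at 1.26 ± 0.17. Of 21 fibroblast and matrix genes 7 fell and 1 rose (4 and 1 when adjusted over the list alone, 9 and 0 without TMM factors). Their median (-0.14) and mean (-0.41) were below 0 while camera gave the direction as up (adjusted p = 0.373). The count of falls depended on 1 virgin library, V502, and on the method. Without V502 2 fell and 6 rose, with a median of 0.42, and with the animal as a block 2 fell and 6 rose. With V502 kept, 2 fell and 3 rose with DESeq2 (median 0.06) and also with limma-voom (median 0.35). COL1A1, a collagen chain, had a log2 fold change of -1.87 ± 0.61 (edgeR adjusted p = 0.00998), of -0.21 without V502 (adjusted p = 0.651) and of 0.00 with the block (adjusted p = 0.995), and was lower in 7 of 15 animals. POSTN, a matrix protein, fell by 2.03 ± 0.29 and was lower in 14 of 15 animals.

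**Figure D3:**
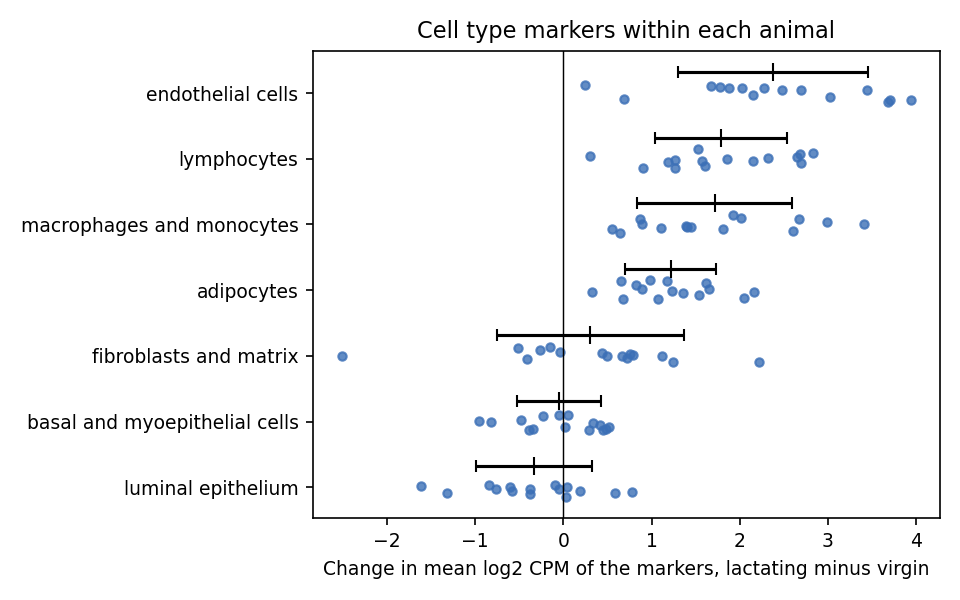
Change in the mean log2 CPM of the markers, lactating minus virgin library of the same animal (x axis), for each cell type list (y axis). Points are the 15 animals and black bars are mean ± SD. The endothelial change was 2.38 ± 1.08 and the luminal change -0.33 ± 0.65.

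Interferon response genes rose in 10 of 18 cases, also when adjusted over the list alone, and 8 were not called, while 9 rose and 3 fell without TMM factors (camera adjusted p = 4.41e-05; adjusted p = 0.192 with an estimated correlation). IFIH1, a sensor of double-stranded RNA, rose by 1.86 ± 0.16 and RSAD2, an antiviral enzyme, by 2.27 ± 0.30. Acute phase and antimicrobial genes rose in 13 of 18 cases and fell in 1, with the same counts when adjusted over the list alone (camera adjusted p = 1.19e-04; adjusted p = 0.218 with an estimated correlation). CCL2, a monocyte-attracting chemokine, rose by 2.56 ± 0.27 and LBP, which binds bacterial lipopolysaccharide, by 2.49 ± 0.32, each in 15 of 15 animals, and PGLYRP1, a peptidoglycan recognition protein, fell by 2.06 ± 0.37. Of 11 antigen presentation genes 2 rose, also when adjusted over the list alone, and 4 with the animal as a block, while 2 rose and 2 fell without TMM factors. Their median was 0.08, and -0.29 without TMM factors (camera adjusted p = 0.0889, and 0.0408 without V479 and V490). B2M, the light chain of class I molecules, rose by 0.87 ± 0.17 over a locus 2.49 times its RefSeq length. PSMB8, an immunoproteasome subunit, stood at 0.37 ± 0.22 (edgeR adjusted p = 0.146). Its adjusted p was 0.0136 with the block and 0.0248 without V479, and its value -0.06 without TMM factors. BOLA-DMB, of the class II loading complex, stood at 0.54 ± 0.26 (edgeR adjusted p = 0.0727). Its adjusted p was 0.00497 with the block, 0.0492 without L478 and L538, 0.0205 without V479 and V490, and 0.0116, 0.0247 and 0.0208 without V478, V479 and V581 in turn. Of 20 immediate early and heat shock genes 6 rose and 1 fell, also when adjusted over the list alone, and 1 rose and 7 fell without TMM factors. The median of the list was 0.16, and -0.28 without TMM factors. Camera gave the direction as up relative to the other genes in every case (adjusted p = 0.0718, and 0.00932 without V479 and V490 and 0.0323 without TMM factors). Without the animals whose virgin library has a lettered title 2 rose and 1 fell. EGR2, an immediate early transcription factor, rose by 0.93 ± 0.25, a call lost without TMM factors (0.58, adjusted p = 0.0645). The member that fell was HSPA1A, a heat shock chaperone (-2.19 ± 0.60, edgeR adjusted p = 0.00274, lower in 7 of 15 animals, and -1.59 without V478), a call lost with the animal as a block (-0.48, adjusted p = 0.570).

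Of the 26 lists tested, 11 passed camera with the preset correlation. With an estimated correlation 0 lists were called, and 6 had an unadjusted p under 0.05. Lists that gained a camera call in another setting did so with the preset correlation. Against this, 19 lists were called by fry, which does not compare a list with other genes.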

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

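The settings that leave out chosen or single libraries, count each repeated locus once or every row in the total, join the block with an estimated correlation, or test the lists on the block's 30 libraries without the block were chosen after seeing the data, and the others before the data were examined. Without TMM factors 1389 rows were higher and 7751 lower, 342 and 1033 of them over 2-fold, and camera called 17 lists. Of the 7258 calls reported, 5458 were called in the same direction there and 5 in the other. Also without TMM factors, PSMB8 stood at -0.05846, STAT5A at -0.2534 and STAT5B at -0.3644, against values above 0 with them, and the basal and myoepithelial list turned from down to up (adjusted p = 0.989). Without the animals whose virgin library has a lettered title, 469 rows were higher and 234 lower over 2-fold, from fewer libraries. Rows lower over 2-fold numbered 245 with DESeq2 and 197 with limma-voom. The number of lists called was 0 with an estimated correlation, 0 with the block and an estimated correlation (camera), and 19 with fry. With the animal as a replicate block 3666 rows were higher and 3656 lower, 870 and 326 over 2-fold, and 6698 of the calls reported were called in the same direction. COL1A1 turned to 0.004319 (adjusted p = 0.995), the calls of PRLR and HSPA1A were lost, and those of PSMB8, BOLA-DMB and the lactose list were gained, with no other change of call among named genes and lists. That fit also lacks L495, and without L495 and without the block PRLR alone changed (-0.5501, adjusted p = 0.0606). The milk protein share difference was 23.9 points within animals (two-sided permutation p = 6.10e-05, the smallest that sign flips of 15 animals can give). Over every setting run, that difference kept its direction and call at 17.4 to 31.3 points. With other size factors (DESeq2 or upper quartile), the milk proteins left out of the scaling or another filter on low counts, 2809 to 3424 rows were higher and 3608 to 4335 lower, and the neutrophil list gained its call with the stricter filter. Where no value shows the cause of a change, the cause was not tested.

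Leaving out each of the 31 libraries in turn gave 3044 to 3637 rows higher and 3914 to 4307 lower. Over 2-fold, these ranges were 663 to 869 and 336 to 401. Over the settings other than these, the 134 named genes gave 2267 values. Of these 2233 kept the direction and the side of the threshold, 23 lost the call, 7 gained one and 4 turned. Scaling by spike-in RNA was not run. The scaling cannot be checked against an outside standard here, so a change common to most genes cannot be seen.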

Other observations

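All genes named in the next paragraph were chosen after their values were seen, and all tests of explanations given after it were chosen after the results were seen.

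Several genes outside the fixed lists differed between the stages. IRF1, a transcription factor of the interferon response, rose by 2.42 ± 0.16 on the log2 scale (SE; edgeR adjusted p = 5.74e-13). TLR2, a receptor of bacterial lipoproteins, rose by 3.52 ± 0.26, OSMR, the oncostatin M receptor, by 1.74 ± 0.12, the chemokine CXCL10 by 2.79 ± 0.26 and NFKB1 by 1.42 ± 0.13, each in 15 of 15 animals. CYP24A1, which breaks down active vitamin D, rose by 3.21 ± 0.39, while TRPV6, a calcium channel, fell by 2.95 ± 0.37. FOLR1, a folate receptor whose locus here is shared with FOLR3, rose by 5.58 ± 0.68 and the glutamate transporter SLC1A2 by 4.82 ± 0.75. CRNN, an epithelial differentiation gene, fell by 7.78 ± 0.77 from 7.02 CPM, and SLIT1, a guidance ligand, fell by 4.35 ± 0.27. The activin antagonist FST fell by 2.56 ± 0.41, the growth factor EREG fell by 1.94 ± 0.37 and tissue factor F3 fell by 2.07 ± 0.26.

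Libraries L478 and L538 held few milk transcripts, with the mean of CSN1S1, CSN1S2, CSN2, LALBA, PAEP and GLYCAM1 193-fold and 431-fold below the lactating median, but CSN3 only 9.32-fold and 22.5-fold and XDH only 2.69-fold and 2.95-fold below it. The tables argue against virgin libraries under a lactating label: on 375 genes lowered in the other animals, the lower of both stood at 0.792 between the virgin (0) and lactating (1) medians, above the highest virgin library (0.278), although on 720 raised genes they stood at 0.522 and 0.503. They also argue against dilution by cells without luminal markers as the whole cause, since the lower of both luminal marker scores lay 0.739 log2 units above the lactating median. The score was also 0.243 to 0.441 above that median in L504, L531, L581 and L615, other libraries low in milk transcripts, but at -0.199 in L490. A smaller dilution could therefore be hidden. Luminal cells that make little milk would not lower this score, so it cannot decide on a larger share of such cells. Carry-over from other libraries stays open for the first 6 of these genes alone, which kept the lactating ratio (SD of their offsets at most 0.360, against 0.0804 to 0.481 in the other lactating libraries), a ratio that milk made in these glands would also give, and the stage of the glands at sampling was not tested. CSN3, at 2543 and 1054 CPM, lay above every virgin library and above the 123 and 55.0 CPM that such carry-over would bring, which argues against carry-over as its main source.

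Virgin libraries V479, V490 and V509 held more casein transcripts than most virgin libraries, with CSN2 at 234, 266 and 1208 CPM. In V479 and V490 the same 6 milk genes stood in the lactating ratio, with an SD of offsets of at most 0.415, within the 0.0804 to 0.481 given above for lactating libraries. Carry-over from lactating material is therefore a candidate explanation there, and a small number of cells making milk would give the same ratio. The other virgin libraries had SDs of 1.22 to 2.40. In most of them several of the 6 genes had almost no counts (virgin median 0 CPM for GLYCAM1 and 0.0219 CPM for CSN1S2), so those SDs do not measure a ratio. In V509 the SD was 2.27, beyond the lactating range, which argues against carry-over as the source. No biological explanation was tested for these libraries.

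Endothelial marker scores were higher in the lactating library of all 15 animals. A lower share of epithelial cells would raise fibroblast and matrix markers alike if other cells kept their proportions and expression per cell were unchanged. The tables argue against such a lower share as the whole cause: the endothelial change exceeded the fibroblast change by 2.08 ± 0.792 (SD, n = 15), in 15 of 15 animals. Whether matrix expression per cell changed was not tested, so a lower share joined to such a change stays open. Other values go the way a lower share would: lymphocyte (1.79 ± 0.75), macrophage (1.71 ± 0.88) and adipocyte scores (1.22 ± 0.52) were higher in all 15 animals and the luminal score changed by -0.33 ± 0.65 (SD, n = 15), so a part in the change stays open. The choice among the 5 scalings run is argued against as the whole cause, since the lowest median of the list over them was 1.57, without TMM factors. The other scalings gave nearly the same median as each other (2.125 to 2.168). A shift common to most genes could not be seen with any of them. Among lactating libraries, the endothelial score was 4.56 to 5.52 in those with at least 26.5% of counts on milk protein genes. It was 2.67 to 4.14 in those with at most 11.8%, with L538 (2.67) and L478 (2.68) lowest. No cause of this difference was tested. More vessel tissue in the gland and vessels that separated less well from the organoids stay open, as untested.

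The number of genes called was reached by no other split of the libraries that was run. Of 100 splits into 16 and 15, the real one included, 1 gave as many as 7258 calls, and the highest of the others gave 0 (edgeR; 2724 at an unadjusted p under 0.05, against 7847). Over 2-fold the real split gave 1079 and the highest other 0. Of 100 splits that part every pair, 1 gave as many, and the highest of the others gave 2563 calls and 5 over 2-fold. The others differ from the real split in the number of animals whose stages are swapped. The split with the most calls had 13 of 15 swapped, which is nearly the real grouping with the stage names exchanged. The next, with 2390 calls, had 3 swapped, and splits with 4 to 11 swapped gave 0 calls. In the other splits of both kinds the stage difference adds to the spread within groups, so few calls were likely there. The splits cannot part stage from what goes with it in every animal.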
